A study of Homo sapiens with 16 samples.

How the data were processed

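Total RNA of ME180 cells was measured on Illumina bead arrays after biotin labelling, per the labels' protocols. The series holds 16 arrays in 4 groups of 4: cells given the DMSO vehicle, with no treatment time in the labels, and cells given 10 µM all-trans retinoic acid (ATRA) for 1, 3 or 6 h. Nothing in the labels says that the replicates of a group are separate cultures, so the p-values measure the spread between these arrays, possibly technical. The labels name no slide or scan date.

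The deposited value table holds 1 log2 value per probe and array. The submitters' processing notes name limma, with no role or version; the background correction, the offset and the base of the logarithm are not given in the sources used here. Base 2 was taken because the highest value, 14.73, then stands for a linear intensity of 27246, against 2.50e+06 with base e; every fold below rests on that reading. The values were already quantile normalized by the authors: at equal rank the arrays differed by at most 0.0181 on the log2 scale over the lower 99 percent of ranks. The direction of the scale was taken as brighter probes having higher values, and the genes were not centred. The lowest value was 4.235 in every array, the medians lay near 4.74, and between 13875 and 13881 probes per array, 29.4 percent, reached 6. The deposited table of non-normalized values was used only for its row order. Its 32 value and detection columns carry names that match no sample label, so they could not be assigned to samples and were not used. The analysis had been planned from that table, with normexp background correction, quantile normalization and a filter on detection p-values; the deposited log2 values replaced it, and the filter became a log2 value of at least 6 in at least 4 of the 16 arrays. This filter was chosen after the files were seen and before any model was fitted.

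The rows of the 4 arrays numbered replicate 1 were displaced. In the row order of the non-normalized table, the values of these arrays from row 10570 of 47230 onward, 77.6 percent of the rows, stood 1 row too low. Before that row the mean of the replicate 1 arrays correlated with the mean of the other arrays at r = 0.979 across probes; after it r was 0.325 as deposited and 0.979 once the values were moved up by 1 row. Probes are not independent replicates, so these correlations describe the tables. In windows of 2000 rows, 68 of 68 replicate 1 windows after the break correlated best at an offset of 1 row, 20 of 20 before it at 0, and 276 of 276 windows of replicates 2 to 4 at 0. The replicate 1 arrays carried the misplaced names: among 4495 genes with at least 2 probes in the displaced rows, r between probes of a gene was 0.210 in these arrays as deposited, 0.609 once moved and 0.561 in replicates 2 to 4. All results use the moved values, and the last row, which then had no replicate 1 value, was left out. Single arrays placed the break between rows 10570 and 10572, where no value exceeded 4.71, so its exact position touches no tested gene. On simulated data the search found 20 of 20 displacements within 5 rows, the largest miss being 1 row.

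After the move the replicate 1 arrays still differed from the others in level. With groups in the model, 6590 of 12467 genes and probes (52.9 percent) differed between the replicate 1 arrays and the rest, 2780 higher and 3810 lower, with a median absolute difference of 0.436 on the log2 scale. The replicate 1 arrays were therefore treated as a technical set that holds 1 array of each group. Where a single replicate 1 array is left out, its group no longer holds an array of this set, while the other groups do. The difference in level then enters the comparisons of that group, so a call moved in this way may reflect the set. Beside the count of a comparison the text gives the count with this array set as a block and the count without the replicate 1 arrays, and for a list's members it gives these counts where they differ from the count over all arrays; within the replicate 1 set, with 1 array per group, no test could be made.

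Of the probes, 30113 had 1 gene symbol in the platform annotation given, 8 had several and 17109 were not listed there and stayed unnamed. Symbols were checked through the gene ID against a RefSeq gene table and 0 changed. Of 434 list genes, 392 had a probe. For a gene with several probes passing the filter, the probe with the highest mean over the 16 arrays was used. Of the 49 fold changes named by size or as passing members of the retinoid lists, 10 had a further probe, which had the same direction in each case. Probes without exactly 1 symbol entered under their own identifier. The fit held 12467 genes and probes (9651 with a symbol and 2816 without), taken from 15271 probes. No genome was used.

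Differences between groups were tested with limma 3.58.1 in R 4.3.3: lmFit and eBayes without a trend, 1 model with the 4 groups over all 16 arrays (12 residual and 3.041 prior degrees of freedom), two-sided, with Benjamini-Hochberg adjustment over all genes tested and a threshold of 0.05. The comparisons were 1, 3 and 6 h against DMSO, 3 h against 1 h, 6 h against 3 h, and an F-test over the 3 times. Every adjusted p below comes from these limma fits unless a list test is named. The spread of a group is given as SD over n = 4 arrays and that of a log2 fold change as its standard error (SE). The number of arrays limits the precision. Where every array of a group lay under 6, the fold is given as a lower bound, computed against a value of 6. Where only some did, the fold is printed as measured though it lies near this limit. Among others this holds for CCN2, CCL20 and FOSL1 in DMSO, SOX2 at 1 h and VAV3 at 3 h. Gene names follow a rule fixed before the data were examined: the 10 largest rises and falls per time against DMSO (5 for times compared with each other) among genes past the threshold with 1 symbol and all 4 arrays of a group on one side of all 4 of the other; every passing member of the 3 lists on retinoid metabolism, retinoid receptors and retinoic acid-induced targets; up to 4 members with the smallest adjusted p of any other list.

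The 23 gene lists were fixed together with that rule, from general knowledge. They cover retinoid metabolism and transport, retinoid receptors and coregulators, retinoic acid-induced targets, HOX genes of the 3' cluster ends, squamous differentiation, basal keratinocyte markers, simple epithelial markers, immediate-early and AP-1 genes, NF-kappaB and inflammatory cytokines, interferon response, cell cycle, cell cycle inhibitors, apoptosis, TGF-beta and BMP signalling, Wnt and Notch signalling, sterol synthesis, unfolded protein and heat shock response, circadian clock, hypoxia and glycolysis, markers of fibroblasts, immune cells and endothelium, and housekeeping genes. The 19 lists with at least 5 measured members were tested with camera in limma at a preset inter-gene correlation of 0.01, two-sided, adjusted over the 19 lists of a comparison, and again with an estimated correlation and with fry. Of the 16 tests that passed out of 57, 2 held with an estimated correlation, both at 1 h. Because 1, 3 and 6 h share the DMSO arrays, overlaps between times were set beside 100 simulations. In these every group was drawn unchanged, and the times shared a simulated DMSO group.

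The fit was tested on simulated data built on the 3 h comparison with 12467 genes over 10 runs: 42.9 percent of 2-fold and 86.5 percent of 4-fold changes were recovered, 4.50 percent of calls were unchanged genes, and the unchanged 1 h comparison had a median of 0 calls. Camera called 10 of 10 lists of 20 genes shifted by 0.5 on the log2 scale and 0 of 10 unchanged lists. The simulated genes were drawn independently, so this does not show how camera behaves where the genes of a list correlate. The alternatives changed the filter, the probe choice, the variance model, array weights, the replicate number as a block, the groups in the fit, the threshold, the list test, and left out each array in turn. Chosen only after the data were seen were the rows as deposited, the array set as a block, the replicate 1 arrays or the 6 h arrays left out, filters at 5 and 7, a larger offset, cyclic loess on top of the deposited normalization, and leaving out single arrays for the list tests and the overlap. Tables and plots were made with Python 3.11.15, pandas 2.3.3, numpy 2.4.6 and matplotlib 3.10.9.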

Results

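Gene expression was measured in ME180, a human cervical epidermoid (squamous) carcinoma cell line derived from an omental metastasis. All-trans retinoic acid is the vitamin A metabolite that binds the nuclear retinoic acid receptors. The series follows its effect over time: 4 arrays of vehicle-treated cells and 4 arrays each after 1, 3 and 6 h at 10 µM. The vehicle arrays have no time of their own, so time after the addition is not matched by a control. Values are quantile-normalized log2 intensities of an Illumina bead array, with the rows of the replicate 1 arrays moved by 1 to undo a displacement in the deposited table. Differences were tested with limma over 12467 genes and probes. At each gene named as changed, all 4 arrays of one group lay on one side of all 4 arrays of the other, except where stated.

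**Figure D1:**
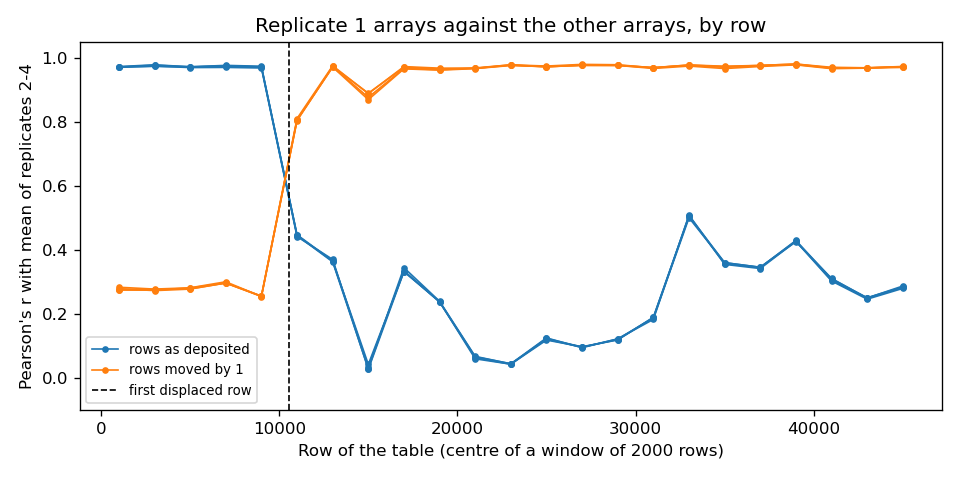
Pearson's r across probes between each replicate 1 array and the mean of replicates 2 to 4 (y axis) by row of the table in windows of 2000 rows (x axis), with rows as deposited (blue) and moved by 1 (orange); 1 line per array, nearly superimposed. The dashed line marks row 10570, after which the deposited rows no longer match those of the other arrays.

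The comparison of 1 h with DMSO asks which genes respond first. Immediate-early genes were among the largest rises. FOSB, a subunit of the AP-1 transcription factor, stood at a log2 intensity of 11.89 ± 1.56 (SD, n = 4) at 1 h against 6.19 ± 0.21 in DMSO, a 52.0-fold rise (log2 fold change 5.70, SE 0.63, adjusted p = 0.00019). CCN2, a secreted matricellular protein, rose 36.3-fold (log2 fold change 5.18, SE 0.33, adjusted p = 4.66e-07), and DUSP1, a phosphatase of MAP kinases, rose 19.6-fold (4.30, SE 0.40, adjusted p = 4.61e-05). The orphan nuclear receptor NR4A1 was below 6 in every DMSO array and at least 4.83-fold higher at 1 h (adjusted p = 2.25e-07). The chemokine CCL20 rose 42.7-fold (log2 fold change 5.42, SE 0.83, adjusted p = 0.00369). Some DMSO arrays lay under 6 for CCN2 (5.71 to 6.70) and CCL20 (5.19 to 7.63), so the size of these folds is uncertain. In all, 71 genes changed, 61 higher and 10 lower. The counts were 117 with the array set as a block (96 higher and 21 lower), 76 without the replicate 1 arrays (69 higher and 7 lower, 59 of them among the 71) and 47 without DMSO replicate 2.

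The other named rises at 1 h were HBEGF, an EGF receptor ligand (18.2-fold), FOS (11.9-fold), RASD1, a Ras-related GTPase (10.8-fold), DUSP5 (10.3-fold) and ATF3 (10.1-fold). The SE of their log2 fold changes lay between 0.33 and 0.51, and their adjusted p was at most 0.0022. The DMSO arrays were split at FOS, with 5.73 and 6.69 in replicates 1 and 4 and 8.43 and 8.69 in replicates 2 and 3 (SD 1.42). The size of the FOS fold is therefore uncertain. Each of the 10 rises kept its call whichever array was left out.

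Of 26 measured immediate-early and AP-1 genes, 16 rose at 1 h and 0 fell (21 adjusted over the list alone, 19 with the array set as a block, 18 without the replicate 1 arrays). With NR4A1, CCN2 and DUSP1, the smallest adjusted p belonged to ZFP36, which binds and destabilizes AU-rich mRNAs (log2 fold change 2.86, SE 0.27, adjusted p = 4.55e-05). The median log2 fold change of the list was 2.04 (camera adjusted p = 4.16e-83; adjusted p = 0.000269 with an estimated correlation, 1.80e-65 with the array set as a block, 9.85e-70 without the replicate 1 arrays). Of 12 measured NF-kappaB and inflammatory cytokine genes, 3 rose at 1 h: IL1A (2.06, SE 0.24, adjusted p = 0.000333), CCL20 and PTGS2, the inducible cyclooxygenase (3.04, SE 0.59, adjusted p = 0.0222). Adjusted over the list alone there were 5, and over all genes 3 with the array set as a block and 3 without the replicate 1 arrays. The list median was 1.01, or 0.71 with a gene under 6 in DMSO put at its bound (camera adjusted p = 6.81e-14; adjusted p = 0.0211 with an estimated correlation, 3.99e-10 with the array set as a block, 2.39e-11 without the replicate 1 arrays). Both list calls held whichever array was left out. In 1 h replicate 1, however, the NF-kappaB list median relative to the DMSO mean was -0.07, within the DMSO range of -0.22 to 0.50. In 1 h replicates 2, 3 and 4 it was 0.77, 2.02 and 1.11.

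Lists with few changed members also passed the camera test at 1 h, and none of these held with an estimated correlation. Of 14 cell cycle inhibitors, 2 rose, the stress-response genes GADD45B (log2 fold change 2.35) and GADD45A (1.76), 2 adjusted over the list alone (camera adjusted p = 0.00432; 0.149 as the adjusted p with an estimated correlation). Of 10 circadian clock genes, 2 rose, the transcriptional repressor BHLHE40 (2.92, SE 0.40, adjusted p = 0.00152) and PER2 (1.14), 2 adjusted over the list alone and 1 without the replicate 1 arrays (0.00432; adjusted p = 0.132 with an estimated correlation; 0.0894 without DMSO replicate 1). Of 12 hypoxia and glycolysis genes, ANKRD37 rose (1.63), 1 adjusted over the list alone (0.00432; adjusted p = 0.149 with an estimated correlation; 0.141 without DMSO replicate 1). Of 13 TGF-beta and BMP genes, the corepressor TGIF1 rose (1.28), 1 adjusted over the list alone (0.0210; adjusted p = 0.196 with an estimated correlation; 0.330 without DMSO replicate 1, and lost also without 1 h replicate 4). Of 18 retinoic acid-induced targets, BHLHE40 alone rose, 2 adjusted over the list alone (0.00872; adjusted p = 0.472 with an estimated correlation; 0.330 without DMSO replicate 1, and lost also without 1 h replicate 3 or 4). Of 10 simple epithelial markers, 0 rose, 1 adjusted over the list alone (0.0447; adjusted p = 0.149 with an estimated correlation; 0.109 with the array set as a block; 0.0786 without the replicate 1 arrays), and its median fell below 0 with a dim member put at its bound. That last call was also lost without DMSO replicate 1 or 3, 1 h replicate 1, 3 or 4, 3 h replicate 1 or 6 h replicate 4 (highest adjusted p 0.227, without 1 h replicate 4). With the array set as a block or without the replicate 1 arrays, the camera adjusted p of the other 5 lists lay between 0.00655 and 0.0205. Leaving out DMSO replicate 1 alone takes the array set out of the vehicle group only. The calls lost without that array may therefore reflect the set.

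Among genes that fell at 1 h, SOX2, a transcription factor of stem and squamous progenitor cells, had the largest change. Its log2 intensity was 5.92 ± 0.30 (SD, n = 4) against 7.56 ± 0.38 in DMSO (log2 fold change -1.64, SE 0.26, adjusted p = 0.00498); a second SOX2 probe gave -1.23 with an adjusted p of 0.269. INKA1 (2.64-fold lower) and the homeobox gene ISL1 (2.26-fold lower) fell as well, and the calls of these 3 genes held whichever array was left out. The named falls also held HILPDA, a lipid droplet protein (2.10-fold), the zinc finger genes ZSCAN2 (2.29-fold), ZNF211 (2.13-fold), ZNF416 (1.84-fold) and ZNF564 (1.76-fold), the ephrin ligand EFNA4 (2.00-fold) and PARS2, the mitochondrial prolyl-tRNA synthetase (at least 1.43-fold). The EFNA4 call was not shared by its other probe (log2 fold change -0.67, adjusted p = 0.545). These 7 calls depended on single arrays. Without 1 h replicate 4 the adjusted p was 0.0575 for ZSCAN2, 0.0589 for ZNF211, 0.0915 for PARS2, 0.0993 for EFNA4, 0.190 for ZNF416 and 0.204 for ZNF564, and without DMSO replicate 2 it was 0.0675 for HILPDA. ZNF416 and ZNF564 lost their calls without any of 12 of the 16 arrays, that is, all but 1 h replicate 2, 3 h replicate 1, 6 h replicate 4 and, for ZNF416, 6 h replicate 2 or, for ZNF564, 3 h replicate 2. HILPDA lost its call also without DMSO replicate 1 or 1 h replicate 3, and ZSCAN2 and ZNF211 theirs also without DMSO replicate 2. PARS2 and EFNA4 lost theirs also without DMSO replicate 1, 2 or 4, and then without 1 h replicate 3 for PARS2 and 1 h replicate 1 for EFNA4. Without the replicate 1 arrays ZNF211, PARS2, ZNF564, EFNA4 and ZNF416 did not pass (adjusted p between 0.0556 and 0.185). Over the 15 other settings tried, the adjusted p of these 7 genes ranged from 0.000306 to 1, the highest with the rows as deposited.

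**Figure D2:**
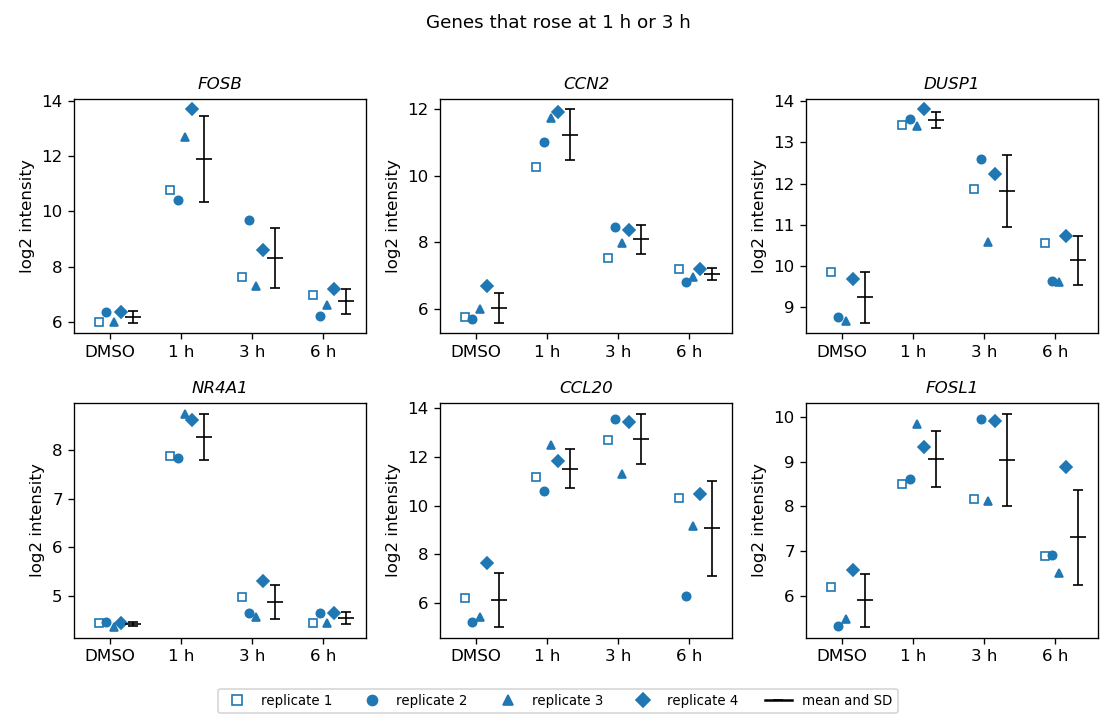
Log2 intensity (y axis) of 6 genes that rose at 1 h or 3 h in each array by group (x axis). Open squares are replicate 1 arrays, filled symbols replicates 2 to 4, and black bars the mean and SD of 4 arrays; NR4A1 lies near 4.43 in DMSO, at 8.27 at 1 h and near 4.88 at 3 h.

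At 3 h, inflammatory cytokines and a retinoic acid-degrading enzyme were among the largest rises. CCL20 stood at 12.75 ± 1.03 (SD, n = 4) against 6.11 ± 1.10 in DMSO, a rise of 100.2-fold (log2 fold change 6.65, SE 0.83, adjusted p = 0.00252). CYP26B1, a cytochrome P450 that hydroxylates retinoic acid, rose 28.9-fold (4.85, SE 0.93, adjusted p = 0.0291), and the cytokine IL1B rose 16.9-fold (4.08, SE 0.82, adjusted p = 0.0408). IL36G, an epithelial cytokine of the IL-1 family, rose 9.60-fold (3.26, SE 0.38, adjusted p = 0.00166), and the phosphate transporter SLC20A1 rose 5.95-fold (2.57, SE 0.36, adjusted p = 0.00576). In all, 65 genes changed at 3 h, 54 higher and 11 lower. The count was 384 with the array set as a block (234 higher and 150 lower), 94 without the replicate 1 arrays (65 higher and 29 lower, 46 of them among the 65) and 117 without the 6 h arrays in the fit (94 higher and 23 lower). Single arrays moved it too: it was 28, 15 and 19 without DMSO replicate 1, 2 or 3, and 15 and 20 without 3 h replicate 2 or 4. Without DMSO replicate 1 the vehicle group held no array of the replicate 1 set, so the 28 may reflect the set.

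The other named rises at 3 h were the coagulation initiator F3 (tissue factor, 10.2-fold), the AP-1 subunit FOSL1 (8.76-fold), DUSP1 (5.98-fold), GPRC5A, a retinoic acid-inducible orphan receptor (5.58-fold), and MIR614, a probe for a microRNA gene (at least 3.24-fold). Their adjusted p lay between 0.00166 and 0.0222. The DMSO arrays were split at F3, with 8.56 and 8.32 in replicates 1 and 4 and 6.07 and 5.94 in replicates 2 and 3 (SD 1.41). The size of the F3 fold is therefore uncertain.

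The largest falls at 3 h were VAV3 (log2 fold change -2.87, SE 0.45, adjusted p = 0.01), the homeobox gene DLX5 (at least 3.75-fold lower, adjusted p = 0.00548), SOX2 (at least 2.94-fold lower, adjusted p = 0.000383) and ID2, an inhibitor of basic helix-loop-helix factors (-2.32, SE 0.42, adjusted p = 0.0222). DLX3 (4.43-fold), INKA1 (2.92-fold), the epithelial transcription factor OVOL2 (2.61-fold), PPFIBP2 (2.61-fold), the protein kinase A inhibitor PKIA (2.48-fold) and EPN3 (2.33-fold) were lower as well, with adjusted p between 0.00548 and 0.0460. Further probes of VAV3, SOX2, ID2, PKIA and F3 passed in the same direction.

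Of the 20 named changes at 3 h, those of CCL20, IL36G, MIR614, SLC20A1, SOX2, DLX5, INKA1 and PPFIBP2 kept their calls whichever array was left out. Without DMSO replicate 2 the adjusted p was 0.0534 for DUSP1 and F3, 0.0988 for FOSL1, 0.0998 for ID2, 0.114 for GPRC5A and OVOL2, 0.123 for PKIA and 0.188 for DLX3. Without 3 h replicate 2 it was 0.0514 for VAV3, 0.142 for CYP26B1 and 0.185 for IL1B, and without DMSO replicate 3 it was 0.0759 for EPN3. The calls of EPN3, FOSL1, CYP26B1, ID2, GPRC5A, OVOL2, PKIA, IL1B and DLX3 were each lost without DMSO replicate 2 or 3 or 3 h replicate 2 or 4. Those of CYP26B1, ID2, OVOL2, PKIA, IL1B and DLX3 were lost also without DMSO replicate 1, those of GPRC5A, OVOL2, PKIA, IL1B and DLX3 without 3 h replicate 1, and those of GPRC5A, IL1B and DLX3 without DMSO replicate 4. IL1B lost its call also without 1 h or 6 h replicate 4, and DLX3 without any 1 h array or 6 h replicate 3 or 4. F3 lost its call also without 3 h replicate 4 and DUSP1 without 3 h replicate 2. Over the 15 other settings tried, the adjusted p of these 12 genes ranged from 0.000525 to 1, the highest with the rows as deposited. Without the replicate 1 arrays the calls of OVOL2 (adjusted p = 0.0534), CYP26B1 (0.0678), ID2 (0.0705) and IL1B (0.0936) were lost.

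**Figure D3:**
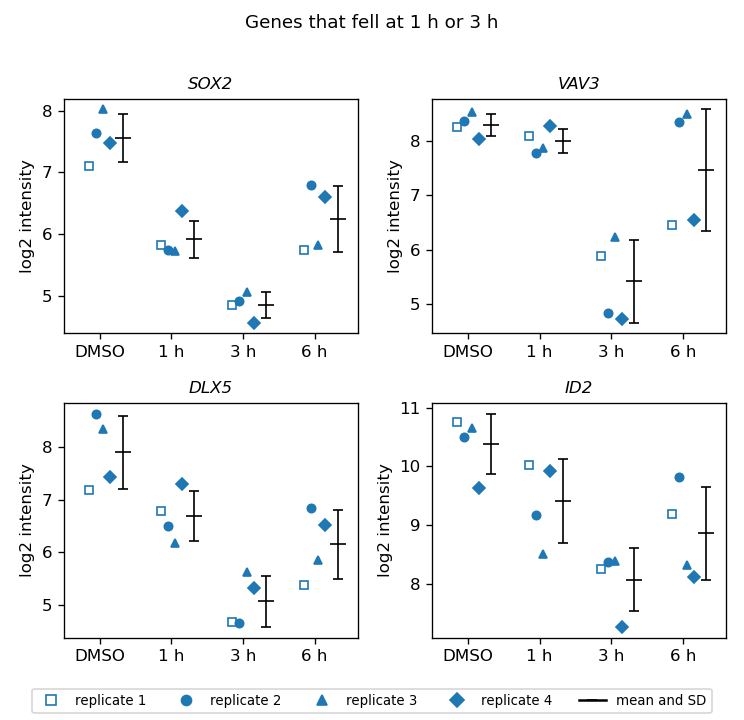
Log2 intensity (y axis) of 4 genes that fell at 1 h or 3 h in each array by group (x axis). Open squares are replicate 1 arrays, filled symbols replicates 2 to 4, and black bars the mean and SD of 4 arrays; SOX2 goes from 7.56 in DMSO to 5.92 at 1 h and 4.86 at 3 h.

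Of 12 measured retinoid metabolism and transport genes, CYP26B1 rose at 3 h, and 2 passed adjusted over the list alone. The second was CYP26A1, named here after its values were seen. It was higher in all 4 arrays (log2 fold change 5.08, SE 1.66) with an adjusted p of 0.266 over all genes. Its arrays lay between 12.18 and 14.02 at 3 h and between 7.26 and 8.83 in DMSO. The SE is pooled over the 4 groups and takes in the 6 h arrays, which ran from 4.53 to 13.13. The list median was 0.22 (camera adjusted p = 0.00661; adjusted p = 0.226 with an estimated correlation; 0.0114 with the array set as a block; 0.0221 without the replicate 1 arrays; 0.0621 without DMSO replicate 1). With the array set as a block 2 members passed over all genes, and without the replicate 1 arrays 0. At 1 h 0 members rose, 1 adjusted over the list alone. CYP26B1 was higher in all 4 arrays at 3.41 (SE 0.93, adjusted p = 0.225). This SE likewise takes in the 6 h arrays, from 6.70 to 11.51. At 1 h the list's median was below 0 and its mean, 0.50, and its test pointed up (camera adjusted p = 0.229). Of 18 retinoic acid-induced targets, 0 changed at 3 h, 0 adjusted over the list alone (median 0.32, camera adjusted p = 0.0529), and 1 rose with the array set as a block. The list passed with the replicate number as a block (camera adjusted p = 0.0431). It passed also without DMSO replicate 2 or 3, 3 h replicate 1 or 3, or 6 h replicate 1, 2 or 3 (lowest adjusted p 0.00506). ELF3 and IRF1 of this list were higher in all 3 h arrays than in all DMSO arrays, and ELF3 also in all 1 h arrays, without passing over all genes. Their 6 h arrays, which enter the pooled SE, ran from 7.92 to 10.92 for ELF3 and from 9.16 to 11.67 for IRF1. Of 9 retinoid receptors and coregulators, 0 changed at 1 h or 3 h (camera adjusted p = 0.604 and 0.675), but at 3 h 2 rose and 1 fell with the array set as a block, and 1 fell without the replicate 1 arrays. At 3 h 1 passed adjusted over the list alone, and the median of -0.08 had the opposite sign to the mean and the test.

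At 3 h, 3 of 26 immediate-early genes were higher than in DMSO, namely DUSP1, CCN2 (log2 fold change 2.04) and FOSL1, and 9 passed adjusted over the list alone (median 0.58, or 0.48 with dim members at their bound; camera adjusted p = 9.52e-14; adjusted p = 0.102 with an estimated correlation, 7.24e-11 with the array set as a block, 2.24e-10 without the replicate 1 arrays). CCL20, IL1A (1.52) and IL1B rose among 12 NF-kappaB and cytokine genes, 5 adjusted over the list alone (median 1.43, or 1.29 with a dim member at its bound; 6.26e-12; adjusted p = 0.0726 with an estimated correlation, 7.94e-09 with the array set as a block, 5.13e-08 without the replicate 1 arrays). Members that rose over all genes numbered 8 and 4 in these lists with the array set as a block, and 3 and 2 without the replicate 1 arrays. Of 10 simple epithelial markers 0 rose, while CLDN7 (0.75), CLDN4 (0.91) and ELF3 (1.69) passed adjusted over the list alone (median 0.41, or 0.23 with a dim member at its bound; camera adjusted p = 0.00661; adjusted p = 0.102 with an estimated correlation). Of 18 apoptosis genes 0 changed, 2 adjusted over the list alone, and 2 rose with the array set as a block (median 0.14, 0.00679; adjusted p = 0.145 with an estimated correlation; 0.0564 without 3 h replicate 2). Of 26 S and G2/M cell cycle genes 0 changed, 0 adjusted over the list alone; their median was -0.20 (camera adjusted p = 0.0149; adjusted p = 0.148 with an estimated correlation; 0.0564 without 3 h replicate 2). Of 17 interferon response genes 0 changed, 0 adjusted over the list alone, and 2 rose with the array set as a block (median 0.07, 0.0485; adjusted p = 0.360 with an estimated correlation; 0.0502 with the array set as a block). That call was lost also without DMSO replicate 1, 3 or 4, 1 h replicate 1, 2 or 4, 3 h replicate 2 or 4, or 6 h replicate 4 (highest adjusted p 0.236, without 3 h replicate 4). With the array set as a block and without the replicate 1 arrays the camera adjusted p was 0.0142 and 0.0277 for simple epithelial, 0.0114 and 0.0130 for apoptosis and 0.0259 and 0.0430 for cell cycle genes, and 0.0369 without the replicate 1 arrays for interferon genes. None of the 3 h list calls held with an estimated correlation.

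The remaining lists did not pass at 3 h. Of 13 TGF-beta and BMP genes, TGIF1 rose (0.98, adjusted p = 0.0493) and ID2 fell, 5 adjusted over the list alone (median -0.19, camera adjusted p = 0.534); 2 fell with the array set as a block and 0 without the replicate 1 arrays, where 1 rose in both. Of 14 cell cycle inhibitors, GADD45B rose (1.35, adjusted p = 0.0222), 2 adjusted over the list alone, 2 with the array set as a block and 2 without the replicate 1 arrays; their median was -0.09 while the mean and the test pointed up (0.675). Squamous differentiation genes (26 measured, among them SCEL at 3 h at 1.52, SE 0.76, and SPRR1B at 0.55, SE 0.47, with arrays that overlap those of DMSO) had 0 changes at any time, with camera adjusted p of 0.229 at 1 h, 0.116 at 3 h and 0.369 at 6 h. Basal keratinocyte markers (11 measured; 0.0974, 0.491 and 0.595) and sterol synthesis genes (11; 0.396, 0.471 and 0.474, with a 1 h median of -0.12 against a mean and test that pointed up) had 0 changes at any time. So did Wnt and Notch genes (16; 0.229, 0.106 and 0.360) and unfolded protein and heat shock genes (15; 0.396, 0.842 and 0.168), except that 2 of the latter fell at 3 h with the array set as a block. Adjusted over the list alone, these 5 lists had 0 members at any time, except HES1 of the Wnt and Notch list at 1 h (0.69) and 3 h (-0.63). Circadian clock (10) and hypoxia genes (12) had 0 changes at 3 h (0.106 and 0.710), 3 and 0 adjusted over the list alone. With the array set as a block 2 clock genes rose and 1 hypoxia gene fell, and without the replicate 1 arrays 1 clock gene rose; the hypoxia median was -0.01 against a test that pointed up. Interferon, cell cycle and apoptosis genes had 0 changes at 1 h (0.580, 0.306 and 0.396), with 0, 0 and 2 adjusted over the list alone; without the replicate 1 arrays 1 interferon gene rose. Without the replicate 1 arrays, the basal markers at 1 h (camera adjusted p = 0.0205) and the Wnt and Notch list at 3 h (0.0394) passed. Leaving out 1 array also brought several of these lists past the threshold: 1 h replicate 1 the basal markers (0.0156) and, as did DMSO replicate 4, the Wnt and Notch list at 1 h (lowest 0.0106). At 3 h, leaving out DMSO replicate 1 or 3 h replicate 4 did so for the Wnt and Notch (lowest 0.0128) and squamous lists (lowest 0.0332), and 1 h replicate 3 for the squamous list at 1 h (0.0477).

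Markers of other cell types were mostly dim. Of the fibroblast, immune and endothelial lists 2, 1 and 2 members passed the filter on dim probes, too few for a list test, and 0 changed at any time; of these 5 genes, CDH5 at 3 h passed adjusted over its list alone, with a mean log2 intensity of 7.03 against 4.44 in DMSO, under the filter's limit (adjusted p = 0.175 over all genes). Of the HOX genes of the 3' cluster ends 3 were measured and 0 changed over all arrays. HOXB5 at 3 h (-0.87, SE 0.30, with overlapping arrays, adjusted p = 0.312) passed adjusted over the list alone and with the array set as a block (adjusted p = 0.0128), and 1 gene of the list fell without the replicate 1 arrays. The 11 housekeeping genes had 0 changes at any time (camera adjusted p at least 0.675), 0 adjusted over the list alone. Their medians were all within 0.02 of 0 and below it, where the tests at 3 h and 6 h pointed up.

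The comparison of 3 h with 1 h asks what changed between the first times of treatment. FOSB fell by 3.58 on the log2 scale (SE 0.63, adjusted p = 0.0231), NR4A1 at least 4.83-fold (adjusted p = 6.61e-07), FOS 10.4-fold (-3.38, SE 0.51, adjusted p = 0.00809), the kinase SIK1 9.57-fold (-3.26, SE 0.46, adjusted p = 0.00457) and CCN2 8.81-fold (-3.14, SE 0.33, adjusted p = 0.000444). PARS2 (at least 1.61-fold), ZNF416 (2.23-fold) and ZNF597 (1.85-fold) were the 3 genes that rose. In all 23 genes changed, 3 higher and 20 lower, against 82 with the array set as a block (27 higher and 55 lower), 18 without the replicate 1 arrays (1 higher and 17 lower, 15 of them among the 23), 36 without the 6 h arrays (12 higher and 24 lower) and 13 without 1 h replicate 4. The calls of NR4A1, FOS, SIK1 and CCN2 held whichever array was left out. That of FOSB was lost without 1 h replicate 3 (adjusted p = 0.111), 1 h replicate 4 or 3 h replicate 1, 3 or 4. Those of PARS2 (0.0699), ZNF416 (0.0556) and ZNF597 (0.117) were lost without 1 h replicate 4, and also without 3 h replicate 4; PARS2 lost it also without 1 h replicate 3 or 3 h replicate 1, and ZNF597 without 1 h replicate 1 or 2 or 3 h replicate 1 or 2. FOSB, ZNF416 and ZNF597 did not pass without the replicate 1 arrays (0.115, 0.0614 and 0.188). Over the 15 other settings tried, the adjusted p of these 4 genes ranged from 0.00251 to 1, the highest with the rows as deposited.

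Genes changed at 1 h and at 3 h overlapped. There were 20 changed at both times, all in the same direction (17 higher and 3 lower). Independent lists would share 0.264 higher and 0.00882 lower genes. Simulated unchanged groups that shared a simulated DMSO group had 0.01 in common on average and at most 1. With no changed gene such groups give few calls, so their overlap cannot show how far the shared DMSO arrays bear on the 20. The overlap was 53 with the array set as a block and 23 without the replicate 1 arrays. Without DMSO replicate 1, 2 or 3 it was 12, 6 and 10, and without 3 h replicate 2 or 4 it was 8 and 11. With different pairs of DMSO arrays for the 2 times it was 0 to 3, with fewer arrays in each comparison. Only 1 of the 2 pairs held DMSO replicate 1. The difference between the array sets then enters the 2 times with opposite signs, which pushes the shared calls down. Across genes, which are not independent replicates, the log2 fold changes at 1 h and 3 h correlated at r = 0.604 (0.501 in the simulation), with a covariance of 0.0801 against 0.0293 simulated, a difference of 0.0507. With different pairs of DMSO arrays for the 2 times r was 0.028 to 0.263, pushed down by the array sets in the same way. How far the shared DMSO arrays account for the overlap is therefore not settled by these pairs. Between 1 h and 6 h r was 0.474, below the 0.4996 of the simulation, and between 3 h and 6 h it was 0.708 (0.502 in the simulation). The covariances were above the simulated ones in both cases, 0.0494 against 0.0292 and 0.0877 against 0.0294.

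At 6 h, limma called 0 genes against DMSO, 0 with the array set as a block or without the replicate 1 arrays, and 0 whichever array was left out. An unadjusted limma p under 0.05 was reached by 548 in the main fit, where the difference between the array sets enters the spread. It was reached by 1416 with the array set as a block and by 1057 without the replicate 1 arrays. With array weights, which weighed 6 h replicate 4 at 0.392 and the replicate 1 arrays at 0.305 to 0.374, 86 genes passed. Against 3 h, 0 genes were called, 0 with the array set as a block, 1 without the replicate 1 arrays, 1 with array weights and 2 without 3 h replicate 3. Here an unadjusted limma p under 0.05 was reached by 424, by 874 with the array set as a block and by 740 without the replicate 1 arrays. Of the 23 lists, 0 members changed. The NF-kappaB and cytokine list passed (median 1.07, or 1.02 with dim members at their bound; camera adjusted p = 6.06e-06; adjusted p = 0.492 with an estimated correlation, 0.000243 with the array set as a block, 0.00419 without the replicate 1 arrays), led by IL1A (log2 fold change 1.06, SE 0.24, higher in all 4 arrays) and CCL20 (2.95, SE 0.83, with overlapping arrays), the 2 that passed adjusted over the list alone. Relative to the DMSO mean, the NF-kappaB list medians in 6 h replicates 1 to 4 were 0.34, 0.12, 0.84 and 1.45. In the DMSO arrays they lay between -0.22 and 0.50, so only replicates 3 and 4 were above that range. TGF-beta and BMP genes had 3 adjusted over the list alone, ID3, ID2 and SMAD6 (camera adjusted p = 0.208), and the circadian clock 1, DBP (0.443). For the other lists tested, with 0 adjusted over the list alone, the camera adjusted p lay between 0.0503 (interferon response) and 0.774. The median of the cell cycle inhibitors, -0.05, had the opposite sign to the mean and the test. Single arrays moved the interferon call (lowest adjusted p 0.000338, past the threshold without DMSO replicate 2 or 6 h replicate 2) and that of the immediate-early list (0.029 without 6 h replicate 3).

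The 6 h arrays differed among themselves at retinoid genes. Of 39 measured members of the 3 retinoid lists, 6 were higher in every 3 h array than in every DMSO array: CYP26A1, CYP26B1, DHRS3, ELF3, NRIP1 and IRF1, singled out after their values were seen. CYP26A1 had log2 intensities of 12.95, 4.53, 13.13 and 5.45 in 6 h replicates 1 to 4, and 7.26, 8.58, 8.83 and 7.79 in the DMSO arrays. CYP26B1 had 10.68, 6.70, 11.51 and 7.12 at 6 h, and DHRS3, a retinal reductase, 12.33, 9.24, 12.69 and 10.27.

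**Figure D4:**
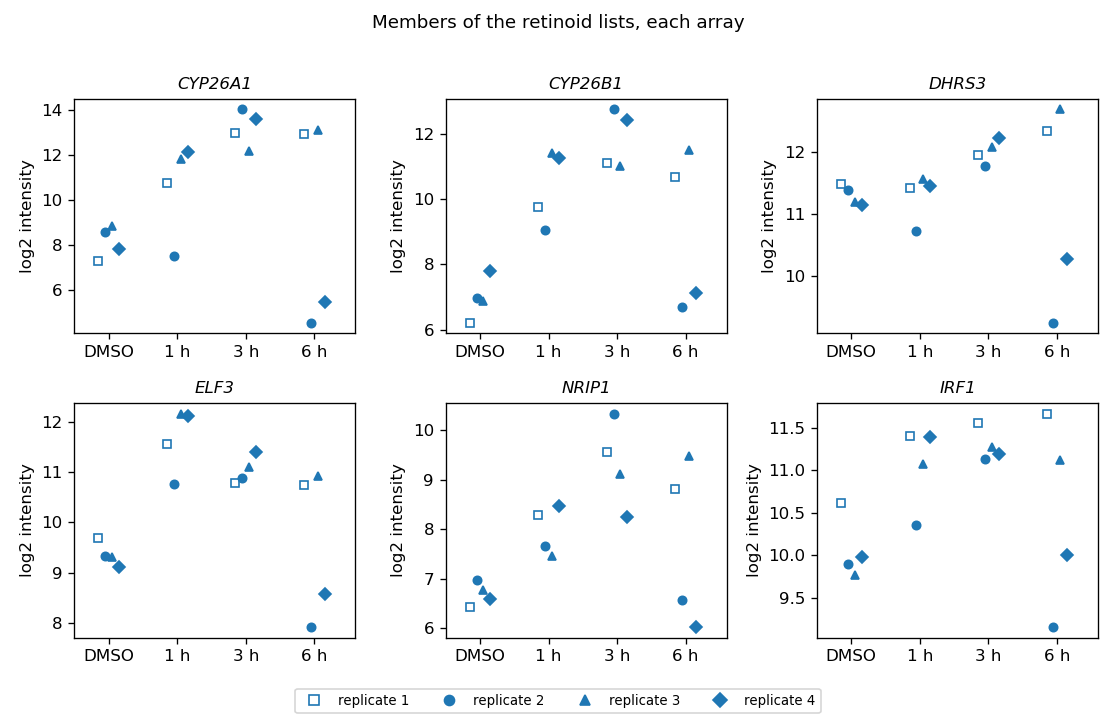
Log2 intensity (y axis) of 6 members of the retinoid lists in each array by group (x axis), with 1 symbol per replicate and open squares for replicate 1. At 6 h the 4 arrays are spread from 4.53 to 13.13 for CYP26A1, so no mean is drawn.

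Over the 3 times together, the limma F-test called 86 genes, 281 with the array set as a block and 76 without the replicate 1 arrays (56 of them among the 86). The count was 51 and 55 without DMSO replicate 2 or 3, and 53 without 1 h replicate 3 and without 1 h replicate 4.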

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

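The search covered 39 genes in 4 groups, those named by size of change or as passing members of the retinoid lists, and not members named from other lists. Among these 156 sets of 4 arrays, 3 held an array whose gap to the nearest other array was large against the range of the set. By chance about 5 percent of sets would. FOSL1 stood at a log2 intensity of 8.89 in 6 h replicate 4, against 6.52 to 6.91 in the other 6 h arrays. ID2 stood at 7.26 in 3 h replicate 4, against 8.25 to 8.39 in the other 3 h arrays. SOX2 stood at 6.37 in 1 h replicate 4, against 5.73 to 5.83 in the other 1 h arrays.

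Expression at 3 h differed from that at 1 h at 23 genes, by a limma test of the times against each other. This equals the test of the difference of the DMSO comparisons. No vehicle array has a time, so a change with time after the addition cannot be told apart from one in the response to ATRA. The log2 fold changes of the named genes were -3.58 for FOSB, -3.40 for NR4A1, -3.38 for FOS, -3.26 for SIK1, -3.14 for CCN2, 1.30 for PARS2, 1.16 for ZNF416 and 0.89 for ZNF597. The negative values are of genes that were higher at 1 h; PARS2 and ZNF416 were among the genes that fell at 1 h. NR4A1 was below 6 in all arrays but those of 1 h, and PARS2 in those of 1 h, so their values are no measured folds.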

How the results depend on the processing

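Leaving out the replicate 1 arrays or the 6 h arrays, the array set as a block, the rows as deposited, the filters at 5 and 7, the offset of 50 and cyclic loess on top were chosen after the data were seen; so were single arrays left out of the list tests and the overlap. Causes were not tested unless named. Counts are for 1 h, 3 h and 6 h against DMSO, 3 h against 1 h, 6 h against 3 h and any time. With the rows as deposited, they were 13, 0, 0, 2, 0 and 11, since the misplaced values enter each group. The array set as a block gave 117, 384, 0, 82, 0 and 281, an overlap of 53, and, without the 6 h arrays, 139, 571 and 214 for 1 h, 3 h and 3 h against 1 h, the last with 104 higher and 110 lower in place of 3 and 20. Leaving out the 6 h arrays alone moved 3 h to 117 and 3 h against 1 h to 36. Without the replicate 1 arrays, 6 h against 3 h moved from 0 to 1. Array weights gave 216, 462 (285 higher and 177 lower), 86, 46, 1 and 434. No filter on dim probes moved 3 h to 25 and any time to 54, with 37163 genes and probes tested. Only the 2 groups compared moved 3 h against 1 h to 8. An adjusted p under 0.01 left 47, 12, 0, 13, 0 and 36. Leaving out each array in turn gave 47 to 72, 15 to 84, 0 to 0, 13 to 30, 0 to 2 and 51 to 99, 11 to 18 passing list tests and an overlap of 6 to 25. Of 57 list tests 16 passed; 2 passed with an estimated correlation and 6 with one-way fry. The overlap of 20 was 0 to 3 with separate pairs of DMSO arrays, of which only 1 held a replicate 1 array.

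The replicate number as a block gave 117, 341 (208 higher and 133 lower), 0, 63, 0 and 245 genes and 16 passing list tests, with retinoic acid-induced targets at 3 h (0.0431) in place of simple epithelial markers at 1 h (0.0859). Of 24 pairs of arrays with the same number 18 correlated over 0.1 in their deviations from the group means. The 6 pairs of replicate 1 had r of at least 0.794, and 12 of the 18 pairs of replicates 2 to 4 were over 0.1 (-0.135 to 0.701). Pairs with different numbers among replicates 2 to 4 ran from -0.234 to 0.745, so values over 0.1 do not set equal numbers apart. The highest of these was between 1 h replicate 3 and 3 h replicate 4. The main fit takes no account of such links. Only 6 of 16 arrays, 2 of them among replicates 2 to 4, correlated best with their own number, a hint from the data and not the design, so the numbers were not taken to pair the arrays.

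This check covered 49 fold changes, those named by size or as passing members of the retinoid lists. Members named from other lists, such as ZFP36, IL1A, PTGS2 and TGIF1, were not in it. Of the 49, 0 reversed with any array left out or under the 15 alternatives. These gave values for all 49 except the filter at 7 (46) and the rows as deposited (47). In all, 26 stayed past the threshold whichever array was left out. The array set, the replicate block, array weights and all probes ended 0 calls, leaving out the replicate 1 arrays 12, only the 2 groups compared 12, no filter 10, the 6 h arrays left out 5, the offset 4, the filter at 5 and the trended robust variance 3 each and cyclic loess 1. The rows as deposited ended 39 of 47. The background correction, offset and cyclic loess planned on the non-normalized values, the detection filter and the slide as a block were not run, since those columns could not be assigned to samples and no slide is named. Signal over background limits genes under 6. Folds of genes under 6 in every array of a group are only bounds, and those of genes under 6 in some arrays are uncertain.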

Other observations

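All tests in this part were chosen after the values were seen, except those of the regroupings of the arrays and of the correlation with the DMSO mean.

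Beyond the named genes, several regulators passed adjusted over their own list and not over all genes. With the array set as a block NRIP1, CASP9, CFLAR, ID3 and BMAL1 passed over all genes at 3 h (adjusted p between 0.00467 and 0.0425), and SMAD6, TGFB3, DBP and HES1 did not. At 3 h the nuclear receptor corepressor NRIP1 was higher in all 4 arrays (log2 fold change 2.62, SE 0.63, adjusted p = 0.0848 over all genes). The initiator caspase CASP9 (2.01, SE 0.47, adjusted p = 0.0734) and CFLAR, which blocks caspase activation at death receptors (1.00, SE 0.26, adjusted p = 0.122), were both higher in all 4 arrays. In the TGF-beta and BMP list, ID3 was lower in all 4 arrays (-1.01, SE 0.24, adjusted p = 0.0766), as ID2 was, SMAD6 was lower on average (-0.92, SE 0.30, adjusted p = 0.266), and the ligand TGFB3 was higher in all 4 arrays (a mean log2 intensity of 7.86 against 5.76 in DMSO, near the filter's limit; adjusted p = 0.142). Of the clock genes, BMAL1 was higher (1.13, SE 0.29, adjusted p = 0.122) and DBP lower (-0.83, SE 0.22, adjusted p = 0.138) in all 4 arrays. HES1, a Notch target, was higher in all 4 arrays at 1 h (0.69, SE 0.18) and lower in all 4 at 3 h (-0.63, SE 0.18), with adjusted p of 0.163 and 0.155.

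In the deposited table the replicate 1 arrays matched the other arrays in the first rows and not in the rest. A displacement by 1 row may be the whole cause of this break: 68 of 68 windows after it matched best at an offset of 1 row. Other RNA or another array batch alone is argued against, since r across probes with the other arrays was 0.979 before the break, where these would lower it too. The smaller difference in level that is left after the move (52.9 percent of genes and probes) stays open, as the labels name no batch. No biological explanation was tested.

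At 6 h the retinoid genes CYP26A1, CYP26B1, DHRS3, ELF3, NRIP1 and IRF1 were above all DMSO arrays in replicates 1 and 3 (6 of 6 genes) and not in replicates 2 and 4. RNA of this series' vehicle cultures under the 6 h label would put both arrays below all DMSO arrays at about 6.67 percent of genes; they were so at 3 of 6, which argues against it, though only at the bound set after these genes were seen, and the genes are not independent. Over the 65 genes called at 3 h, 6 h replicates 2 and 4 had 20.9 and 43.3 percent of the 3 h response. DMSO arrays had at most 16.8 percent, and 6 h replicates 1 and 3 had 63.3 and 50.5 percent. The DMSO arrays took part in the choice of those genes, so their own values are held near 0. Replicates 2 and 4 were not alike outside the retinoid genes: CCL20 stood at a log2 intensity of 6.26 in replicate 2 and 10.50 in replicate 4, against 10.31 and 9.17 in replicates 1 and 3. For a swap within the series, 0 arrays of other groups were out of place. The bound for DMSO and 3 h arrays was a share of 0.5 of the 3 h response. Its genes were called from these same arrays, so it decides little about a swap with them. The bound for 1 h arrays was an immediate-early list median no higher than in DMSO. The lowest 1 h median was 1.63 against at most 0.17 in DMSO, which argues against a swap with a 1 h array. A failed hybridisation would put the correlation with the DMSO mean across genes below the 0.963 to 0.979 of the 1 h and 3 h arrays of replicates 2 to 4. For 6 h replicate 2 it was 0.980, which argues against it. For replicate 4 it was 0.967, within that range but near its lower end. That array's weight of 0.392 was near the 0.305 to 0.374 of the replicate 1 arrays. The weights were fitted without the array set and also fall where arrays of a group disagree, so they do not test the hybridisation. A failed hybridisation stays open for 6 h replicate 4. Material from outside this series, or cultures that differed in how far the response had returned, may still account for the pattern. Neither was tested, and the share of the 3 h response leaves a swap with a DMSO or 3 h array open.

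Of the immediate-early genes 16 rose at 1 h, and these 16 were among the 18 that passed without the replicate 1 arrays; each group holds 1 replicate 1 array, so this tests little. An effect of handling or of a medium change at the start of treatment cannot be told apart from one of ATRA for these 16 genes, because no vehicle array has a time. By the design the same limit holds for every other gene compared with DMSO. A direct response to ATRA therefore remains a hypothesis here.

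Over all splits of the same 8 arrays into 4 and 4, 3 counts were reached by the real split alone, under 5 percent of the splits. Each other split mixes arrays of both groups, which widens the spread of genes that differ between them. For 1 h against DMSO 1 of 35 splits, the real one, gave as many as 71 genes, with 0 the highest of the others. For 3 h it was 1 of 35 with 65 genes against 0, and for 3 h against 1 h 1 of 35 with 23 against 0. These splits leave the array set out of account: only 20 of the 35 keep the replicate 1 arrays of the compared groups apart, a restriction chosen after the results were seen. These 20 are too few for a share under 5 percent, so chance is not excluded once the array set is taken into account. Among them the real values were 71, 65 and 23 and the highest other 0 in each case. For 6 h against DMSO and against 3 h the real count was 0, so all 35 splits give as many by construction and say nothing about chance; the highest others were 1 and 4. Chance is not excluded for the number of passing lists: 2 of 35 splits at 1 h (8 lists, highest other 10), 2 of 35 at 3 h (7, highest other 8) and 23 of 35 at 6 h (1, highest other 7). For the F-test, 5 of 100 splits, the real one among them, gave at least 86 genes. The highest other was 735, so chance is not excluded there. Splits with 735 and 584 genes point to a structure of the samples. They put 3 and 2 replicate 1 arrays in one group. A split with 280 genes also put 3 together, but so did splits with 0 genes. No split was run with the array set as a block, so how far it accounts for these counts stays open. With the array set as a block the real count was 281.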
